A study of Mus musculus with 2 samples.

How the data were processed

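Small RNA of adrenal gland tissue was sequenced in 2 libraries of 1 group, from male B6CASTF1/J mice aged 25 days. Per the labels, total RNA went into a multiplexed microRNA library protocol selecting short molecules. The deposited tables hold raw counts of reads per annotated microRNA gene, not normalised, made by the authors from alignments to mm10 with GENCODE annotation M21, per the text files that accompany the tables. The aligner, its settings and the adapter trimming are not given in the sources used here. Each table opens with 4 summary lines, which name no gene and were kept out of library totals and tests. Each has 3 count columns. Their values showed the first to count reads on either strand, the second on the sense strand and the third on the antisense strand.

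Sense counts were used throughout. At hairpins without an annotated hairpin on the opposite strand, 99.99% and 99.98% of counts in replicates 1 and 2 were sense. At 64 hairpins with such a partner, reads are ambiguous in the either-strand column, and these hairpins held 16.7% and 15.1% of the sense counts. The summary lines put 21.3% and 22.8% of input reads as unmapped, 31.6% and 27.0% as mapped to several places, and 5.73% and 5.99% as outside microRNA genes. Reads mapped to several places were not counted per gene, so hairpins with near-identical copies were undercounted. Of the 2202 genes, 1084 share at least 20 bases with another hairpin, as do 89 of the 352 detected genes and 3 of the 25 most abundant. Positions and host genes came from GENCODE M21, where all 2202 identifiers were found.

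Levels are counts per 1000000 assigned sense counts (CPM), with mean and SD over n = 2. Total counts were 3588361 and 4541373, and a floor of 3 counts was worth 0.836 and 0.661 CPM. Genes with at least 10 counts in both libraries were called detected. Log2 ratios used a pseudocount of 1 CPM. The reads of the libraries were compared per detected gene by an exact two-sided binomial test against the library totals, with Benjamini-Hochberg adjustment and a threshold of 0.05. That test compares the libraries and says nothing of conditions. Intervals are exact (Clopper-Pearson) at 95%. The correlation was bootstrapped over genes 2000 times. The biological coefficient of variation was the square root of the common dispersion in edgeR 4.0.16 with TMM factors and an intercept-only design, with 100 resamples of genes.

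A total of 21 gene lists covered microRNA families, genomic clusters and markers of other cell types or organs. The share of counts of each was taken per library. Lists with at least 3 detected members were compared with 10000 random lists, each member replaced from the 30 genes nearest in mean CPM. Levels of adjacent same-strand hairpins under 10 kb apart were tested by permuting levels 100000 times. Named genes were the 25 with the highest mean CPM, the 5 with the highest and the 5 with the lowest ratio between replicates among detected genes with a mean of at least 100 CPM, and up to 4 leading members of each list. Of the other genes named, Mir148a, Mir101a, Mir101b, Mir802 and Mir1948 were chosen for the liver test before their values were seen. Mirlet7c-1, Mir125b-2, Mir708 and the further muscle hairpins were chosen after theirs were seen.

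The binomial test, the dispersion estimate, the list comparison and the cluster test were tested on simulated data. With 200 of 352 genes changed, the binomial test recovered 54.9% of 1.2-fold, 78.5% of 1.5-fold and 90.3% of 2-fold changes and called 1.35% to 2.37% of unchanged genes. Simulated changes reached 2-fold at most, so these rates do not cover a shift of the totals by a gene such as Mir122, 221-fold apart. Simulated coefficients of variation of 0.05, 0.2 and 0.5 were returned as 0.0500, 0.200 and 0.492. Random lists fell outside the central 95% in 6.5% of draws, and the cluster test gave p under 0.05 in 6% of runs on random levels.

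Alternatives were DESeq2 1.42.0 size factors and edgeR TMM factors, other count minimums, pseudocounts of 0.1 and 10, totals without Mir122, totals of all input reads, the either-strand column, other distances between hairpins and each library left out. The gene lists, the tests of the results section, the naming rule and these alternatives were fixed in advance, while the closing section says which of its own tests were not. Leaving out 9 liver-abundant hairpins, and leaving out hairpins that share bases, were added after the data had been seen. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3.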

Results

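MicroRNA levels were measured by microRNA sequencing in the adrenal gland of male B6CASTF1/J mice, the first-generation hybrid of C57BL/6J and CAST/EiJ, at 25 days of age. The adrenal gland holds a steroid-producing cortex and a catecholamine-producing medulla. There was 1 group with 2 biological replicates, and no treatment or second group against which levels could be set. The labels number the animals separately but give both the same donor entry. SDs therefore measure only the spread between these libraries, which may be technical. Binomial p-values weigh the differences of these libraries against counting error, and permutation p-values compare hairpins within them. Replicate 1 had 8666085 input reads, of which 3588361 (41.4%) were counted on the sense strand of a microRNA gene. Replicate 2 had 10284575 input reads and 4541373 (44.2%) such counts. A count of 0 allowed a level of up to 0.836 counts per 1000000 assigned sense counts (CPM) in replicate 1 and 0.661 CPM in replicate 2. It sets no such limit at hairpins that share bases with another, since reads mapped to several places were not counted. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

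The adrenal microRNA pool was dominated in both replicates by let-7 hairpins, the endothelial Mir126a and the Ppargc1b-hosted Mir378a. Mir122 had the highest mean, 99222 CPM, but that rested on replicate 2, with 197553 CPM against 892 CPM in replicate 1. The 10 most abundant genes held 55.9% ± 5.74 of the counts (SD, n = 2). They were Mir122, Mirlet7g, Mir126a, Mir378a, Mirlet7b, Mir10a, Mirlet7i, Mir143, Mir23b and Mir23a. Of 2202 annotated microRNA genes, 352 reached 10 counts in both libraries, 749 had a count in either, and 1453 had none. In replicate 1, 42 genes held 90% of the counts, and in replicate 2, 41 did.

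Mirlet7g (ENSMUSG00000065440.1), in an intron of Wdr82 on chromosome 9 (mm10, 106178840 to 106178927), reached 87956 CPM ± 11985 (SD, n = 2). Mir126a (ENSMUSG00000065540.1) lies within an annotated exon of Egfl7, an endothelial gene, on chromosome 2 (26591357 to 26591429). Its level was 61812 CPM ± 1433. Mir378a (ENSMUSG00000105200.1), in an intron of Ppargc1b on chromosome 18 (61397835 to 61397900), stood at 60419 CPM ± 2731. It shares at least 20 bases with Mir378c, so reads common to both were not counted for either. Mir126a and Mir378a each face an annotated hairpin on the opposite strand, and their levels rest on the sense column. Mirlet7b (ENSMUSG00000065564.1), in an exon of the noncoding Lncppara on chromosome 15 (85707319 to 85707403), followed at 56760 CPM ± 7347. Mir10a, which lies among the Hox genes of chromosome 11, had 43727 CPM ± 17008, and Mirlet7i had 40783 CPM ± 8289. Mir143, a hairpin abundant in smooth muscle, had 38193 CPM ± 10473. Mir23b and Mir23a stood at 35072 CPM ± 10924 and 35072 CPM ± 11492. These 2 hairpins share at least 20 bases, so their counts rest on the reads that differ between them.

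Ranks 11 to 25 held, in order, Mir26b, Mir375, Mir139, Mir322, Mir10b, Mir22, Mirlet7d, Mir30e, Mir127, Mir21a, Mir99a, Mir30a, Mir335, Mir652 and Mirlet7e. Their mean levels ran from 31448 CPM for Mir26b to 8110 CPM for Mirlet7e. Mir375, known from endocrine cells, had 31192 CPM ± 3095 and lies outside same-strand genes on chromosome 1 (74900658 to 74900721). Mir127, of the imprinted Dlk1-Dio3 region, had 13473 CPM ± 640.2. Mir335, in an intron of the imprinted gene Mest, had 9266 CPM ± 3029. Among the detected genes, 142 lay in an intron and 85 in an exon of a gene on the same strand, and 125 lay outside such genes.

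**Figure D1:**
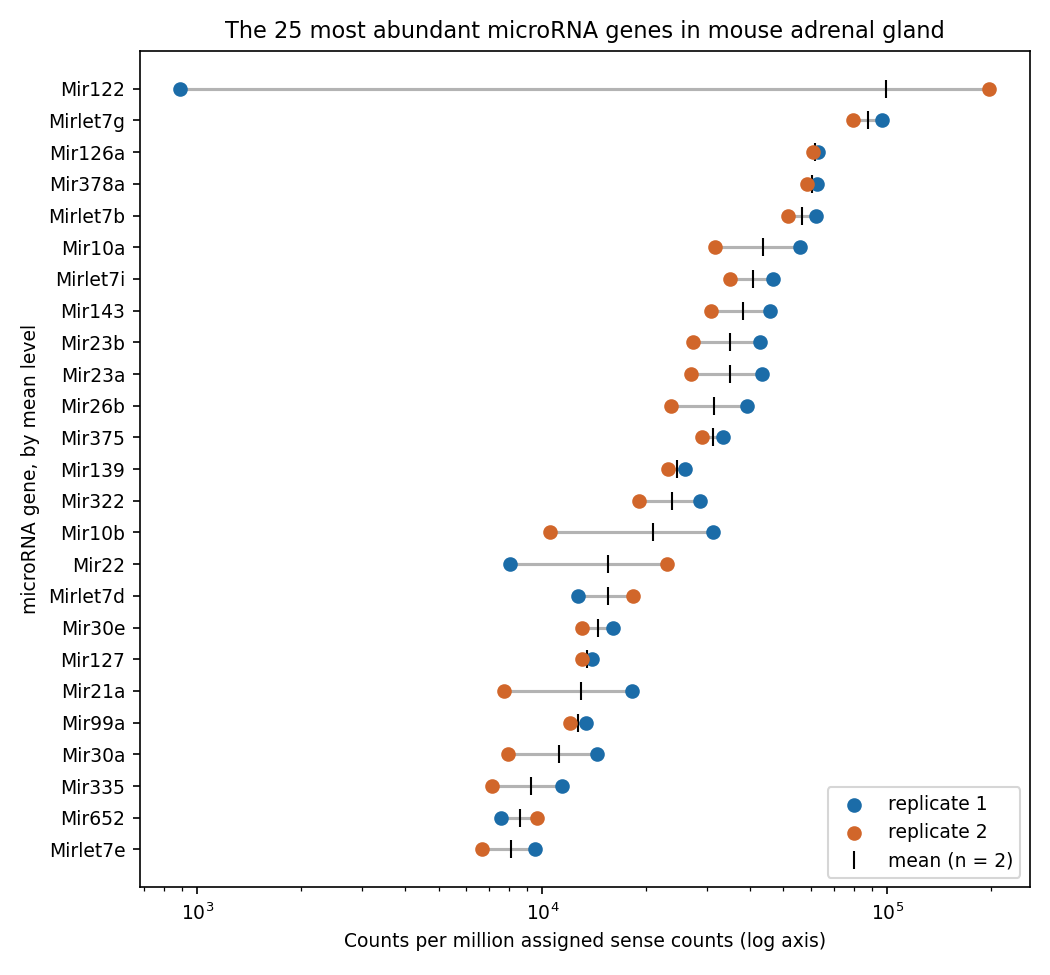
Levels of the 25 most abundant microRNA genes in the 2 adrenal libraries, in CPM on a log axis, with genes ordered by mean. Points are the replicates and the vertical tick is the mean (n = 2). Mir122 spans 892 to 197553 CPM, while Mir126a and Mir378a lie close together in both.

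The 21 gene lists, fixed before the data were examined, showed let-7 with the largest mean share. The liver list, Mir122 alone, came next at 9.92% ± 13.9 (SD, n = 2), nearly all of it from replicate 2, ahead of endothelial, Hox-embedded and adipose-associated hairpins. The 12 let-7 family members, all detected, held 22.1% ± 2.68 of the counts (SD, n = 2), led by Mirlet7g, Mirlet7b, Mirlet7i and Mirlet7d. Of these hairpins 6 share at least 20 bases with another, and their unique counts understate them. The endothelial list held 6.82% ± 0.0243, nearly all of it Mir126a, with Mir130a at 5492 CPM and Mir221 at 714 CPM. The small SD depends on the total, since with Mir122 left out of it the list held 6.81% in replicate 1 and 8.52% in replicate 2. The Hox-embedded list held 6.62% ± 3.13, and the adipose list 6.10% ± 0.267, of which Mir378a made up most. With Mir122 out of the total the adipose list held 6.29% in replicate 1 and 7.36% in replicate 2.

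Hairpins of the imprinted Dlk1-Dio3 region on chromosome 12 (109563692 to 109747960), expressed from the maternal allele in mice, were broadly present, with 46 of 53 detected. They held 4.58% ± 0.565 of the counts. Mir127 led, followed by Mir411 at 6220 CPM ± 90.8, Mir541 at 4544 CPM ± 1224 and Mir379 at 4355 CPM ± 1639. The Mir322 to Mir503 cluster of the X chromosome had all 7 members detected and held 2.63% ± 0.684, of which Mir322 supplied 23816 CPM. The clusters related to Mir17 held 1.08% ± 0.0822, with Mir93 at 3875 CPM and Mir17 at 3055 CPM. The 6 members of the Mir30 family held 3.43% ± 1.04, led by Mir30e, Mir30a and Mir30d.

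**Figure D2:**
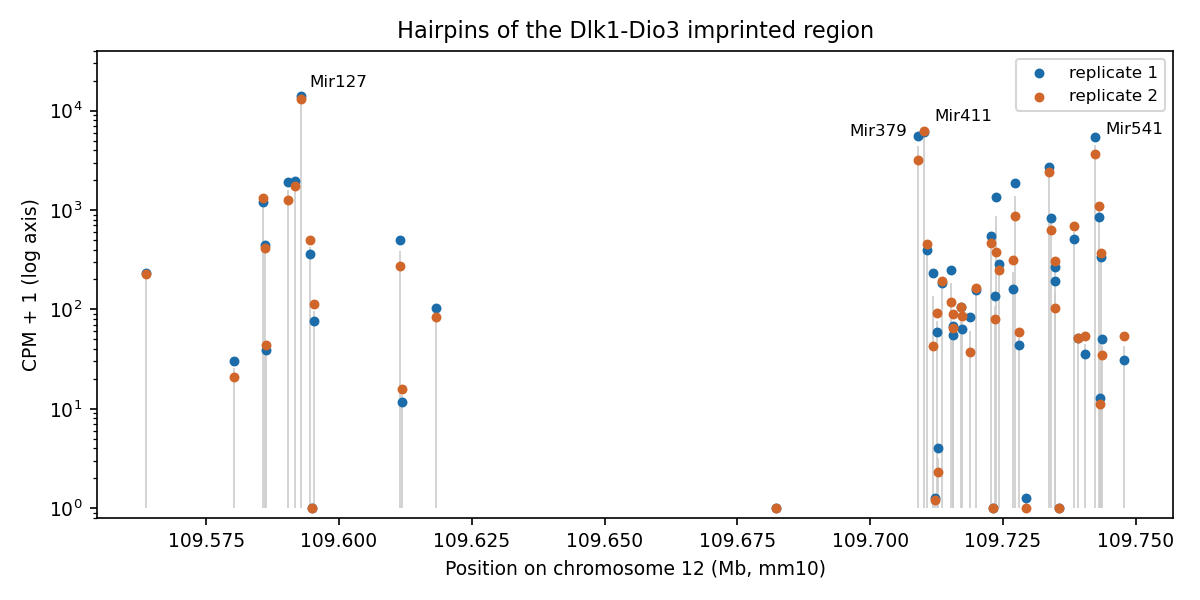
Level of each hairpin of the Dlk1-Dio3 region against its position on mouse chromosome 12 (mm10, megabases), in CPM + 1 on a log axis. Points are the 2 replicates. Mir127 is the highest, and 46 of the 53 hairpins were detected.

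Neuroendocrine hairpins, a list that includes markers of chromaffin cells, held 3.77% ± 0.444 of the counts, with 13 of 19 members detected. Mir375 dominated its counts, and Mir7b at 4884 CPM ± 1131, Mir137 at 539 CPM ± 170 and Mir182 at 446 CPM ± 41.7 followed. Of the 19 members 12 share at least 20 bases with another hairpin, and their unique counts understate them. The undetected Mir9 and Mir124a members are therefore not shown to be absent. The list drawn from adrenal cortex literature held 3.37% ± 0.808, with 16 of 17 members detected. Its highest members were Mir21a at 12947 CPM ± 7381, Mir335, Mir125a at 4437 CPM ± 1901 and Mir320 at 1917 CPM ± 364. The smooth muscle and stroma list held 4.14% ± 1.19, almost all of it Mir143. Its members Mir199a-1, Mir199a-2 and Mir199b share at least 20 bases, and their unique counts understate them.

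Blood cell hairpins were minor parts of the pool. The erythroid list held 0.142% ± 0.0173, led by Mir451a at 1109 CPM ± 139.9, and the leukocyte list 0.392% ± 0.154, led by Mir146 at 1398 CPM ± 361. The epithelial list held 0.230% ± 0.118, led by Mir203, and the ciliated and germ cell list 0.201% ± 0.0925, led by Mir34c at 1854 CPM. The hairpins of the Sfmbt2 cluster type held 0.0975% ± 0.0223, but 78 of its 80 members share at least 20 bases with another hairpin. The testis cluster of the X chromosome had 1 of 21 members detected, Mir547 at 9.70 CPM, and held 0.00107% ± 5.64e-05. Hairpins resembling rRNA or tRNA fragments held 0.00534% ± 0.000854, led by Mir6236.

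Lists for 3 other organs were far from even between the libraries. The liver list is the single gene Mir122, which made up 0.0892% of counts in replicate 1 and 19.8% in replicate 2. The kidney list held 0.0106% in replicate 1 and 0.140% in replicate 2, carried by Mir192 and Mir194-2, which liver expresses too, while Mir204 had 174 and 162 counts. The striated muscle list held 0.101% in replicate 1 and 0.000352% in replicate 2, and 3540 of its 3611 counts in replicate 1 were from Mir206.

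**Figure D3:**
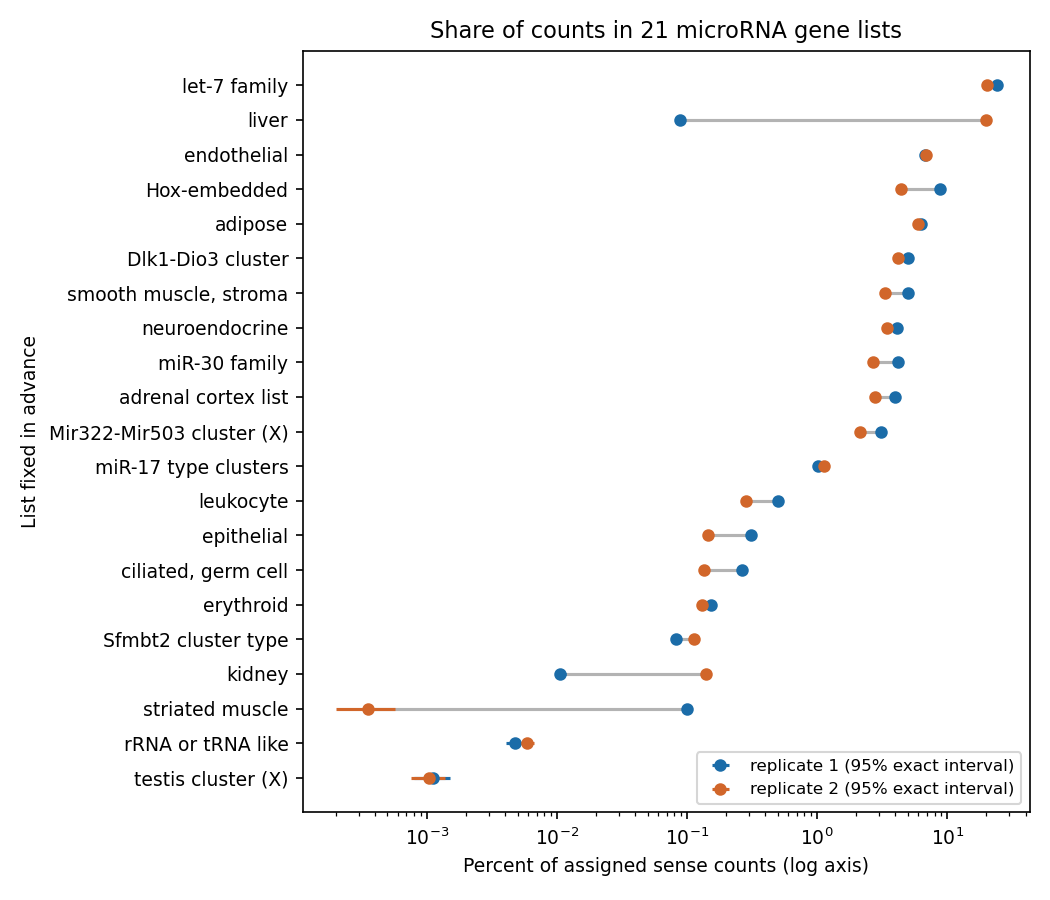
Percent of assigned sense counts in each of the 21 gene lists, on a log axis, in the 2 replicates. Horizontal bars are exact 95% binomial intervals, which cover counting error only. The liver, kidney and striated muscle lists are far apart between replicates, and the endothelial list is at 6.80% and 6.84%, or 6.81% and 8.52% with Mir122 out of the totals.

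Most detected hairpins lay within 2-fold between the replicates, with a Pearson correlation across genes of 0.964 (0.945 to 0.978 from resampling genes) and a Spearman correlation of 0.963. These are over the 352 detected genes, which are not independent replicates. Of them, 293 were within 2-fold, 33 were over 2-fold higher in replicate 2 and 26 over 2-fold higher in replicate 1. The biological coefficient of variation, estimated with edgeR, was 0.422 (0.361 to 0.493 from resampling genes). Leaving out 9 liver-abundant hairpins, a choice made after the values were seen, gave 0.364.

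Among detected hairpins with a mean of at least 100 CPM, those highest in replicate 2 relative to replicate 1 were Mir122, Mir192, Mir194-2, Mir339 and Mir106b. Mir122 (ENSMUSG00000065402.1), the dominant hepatocyte microRNA, lies on chromosome 18 (65248861 to 65248926). It had 892 CPM in replicate 1 and 197553 CPM in replicate 2, a 221-fold difference (214 to 229, exact interval). Mir192 was 29.2-fold (23.0 to 37.5) and Mir194-2 was 21-fold (17.6 to 25.1) higher in replicate 2. Mir339 and Mir106b were 4.69-fold and 4.46-fold higher. Mir22 had 8060 and 22988 CPM in replicates 1 and 2, a 2.85-fold difference, and Mir214 was 4.39-fold higher, against the direction of the other stromal hairpins.

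Among the same hairpins, which leave out Mir206 for having under 10 counts in replicate 2, those lowest in replicate 2 were Mir380, Mir674, Mir376a, Mir145a and Mir142. Mir380 and Mir376a, both of the Dlk1-Dio3 region, were at 0.181 and 0.280 of their replicate 1 levels. Mir674 stood at 0.273, Mir145a at 0.294 and Mir142, a hairpin of blood cells, at 0.314. Mir10b was 2.96-fold higher in replicate 1 (2.93 to 3.00), and Mir21a was 2.35-fold higher there. Mir206, a skeletal muscle hairpin in an exon of Gm28653 on chromosome 1 (20679010 to 20679082), had 3540 counts in replicate 1 and 3 in replicate 2, a ratio of 1493 (511 to 7245).

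An exact two-sided binomial test on the reads of the libraries, adjusted by Benjamini-Hochberg, called 236 of the 352 detected genes at 0.05. It compares these libraries, not conditions. Of the calls, 107 (45.3%) were higher in replicate 2 and 129 in replicate 1. Taking Mir122 out of the library totals moved the median gene by 0.32 on the log2 scale and turned the split to 175 higher in replicate 2 (70%) and 75 in replicate 1. Small differences of a single gene therefore depend on the total used. Under both totals Mir10a, Mir10b, Mir21a, Mir145a and Mir142 were lower, and Mir22, Mir125a, Mir106b and Mir214 higher, in replicate 2.

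**Figure D4:**
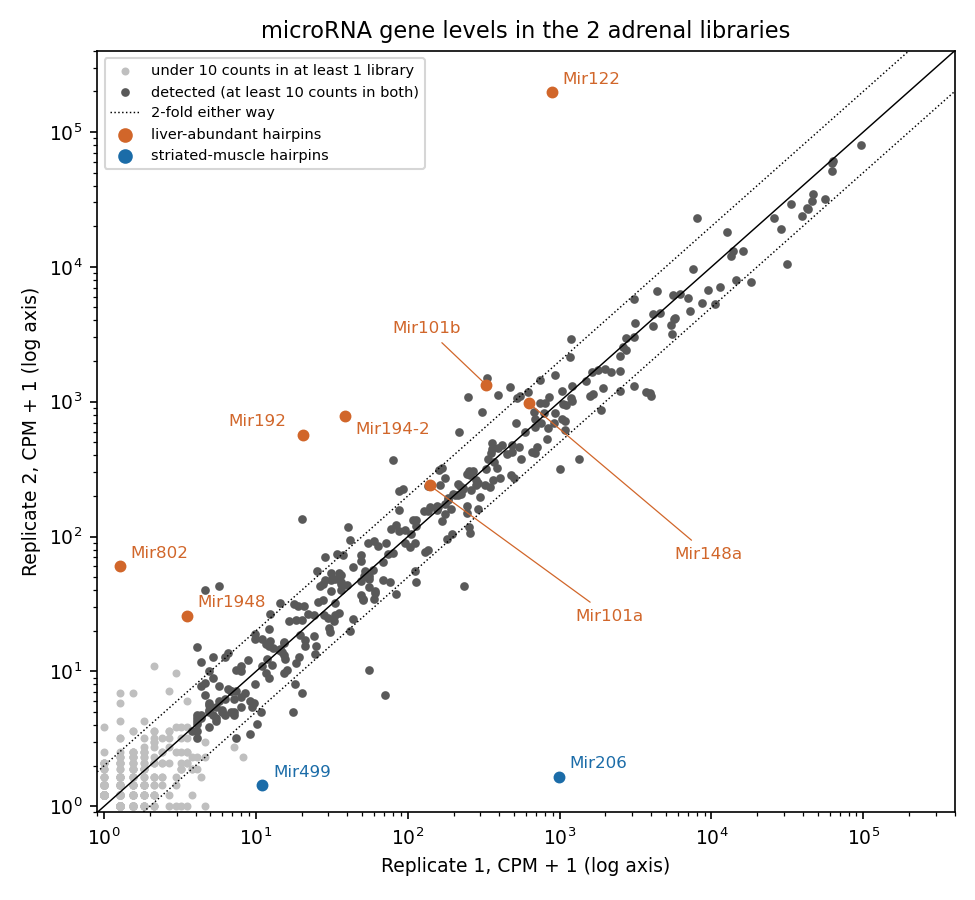
Level of each microRNA gene with a count in replicate 1 against replicate 2, as CPM + 1 on log axes. Dark points are the 352 detected genes, dotted lines mark 2-fold, and liver-abundant and striated-muscle hairpins are named. Mir122, Mir192, Mir194-2 and Mir802 lie far above the diagonal and Mir206 and Mir499 far below it.

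Leukocyte, stromal and Hox-embedded hairpins were lower in replicate 2 than hairpins of like abundance, and kidney-list hairpins were higher. Each list's median log2 ratio, relative to all detected genes, was placed among 10000 random lists matched on abundance. Of 17 lists tested, 4 lay outside the central 95%, where 0.85 would by chance if hairpins varied independently. Neighbours such as Mir192 and Mir194-2 on chromosome 19 may not, and 6.5% of simulated random lists fell outside. The leukocyte median was -0.74 (percentile 0.35), with 6 of 6 members lower, among them Mir142, Mir342, Mir150 and Mir146. All 6 passed the binomial test over all genes and also adjusted over the list alone, and 5 did with Mir122 out of the totals. The Hox-embedded median was -0.62 (percentile 1.02), with 5 of 6 members lower and Mir615, in an intron of Hoxc5, 1.96-fold higher. Over all genes 4 passed as lower and 1 as higher, and 5 and 1 did adjusted over the list alone. The smooth muscle and stroma median was -0.68 (percentile 1.94), with 4 of 5 lower, and with a pseudocount of 10 it was -0.54 (percentile 3.13), inside the central range. Of its members 3 passed as lower and 1 as higher over all genes, and 4 and 1 adjusted over the list alone. The kidney median was 4.39 (percentile 99.7), from 3 detected members of which Mir204 was not higher. Leaving out 1 member gave medians as low as 2.00. Replicate 2 is also the library in which Mir122 made up 19.8% of the counts.

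The remaining 13 lists lay inside the central range. The let-7 median was -0.23, with 9 of 12 members called higher in replicate 1 and 2 in replicate 2 over all genes, and the same numbers adjusted over the list alone. With Mir122 out of the totals 4 were called higher in replicate 1 and 7 in replicate 2. The Dlk1-Dio3 median was -0.02, with 23 members above and 23 below the median gene. Of its 46 detected members 16 were called higher in replicate 2 and 21 in replicate 1, over all genes and adjusted over the list alone, and 26 and 11 with Mir122 out of the totals. Neuroendocrine hairpins gave 4 and 6 calls, and 7 and 5 with Mir122 out, as adrenal cortex hairpins gave 4 and 6, and 9 and 4. The medians were -0.01 for neuroendocrine, 0.11 for adrenal cortex, 0.39 for endothelial (percentile 93.5) and 0.58 for epithelial hairpins (percentile 94.7). In the epithelial list Mir200b was 8.83-fold and Mir429 10.8-fold higher in replicate 2, while Mir203 stood at 0.426 of its replicate 1 level. The others were the Mir30 family (-0.11), the Mir17 clusters (0.15), the Mir322 cluster (-0.35), the Sfmbt2 type (-0.07), the erythroid list (-0.19), the adipose list (-0.0012) and the ciliated and germ cell list (-0.48).

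Neighbouring hairpins had more similar levels than hairpins paired at random. Across 94 pairs of adjacent same-strand hairpins under 10 kb apart, involving 142 detected genes, the mean absolute difference was 2.81 on the log2(CPM + 1) scale. Shuffled levels gave 3.64 (permutation test, one-sided, 100000 resamples, p = 0.00017). The test was not repeated without the Dlk1-Dio3 region, which holds 46 detected hairpins, so this 1 region may carry much of the difference. The level still differed widely inside clusters. Mir143 had 11.5 times the counts of its neighbour Mir145a in replicate 1 and 26.5 times in replicate 2, while Mir451a had 4.32 and 4.24 times the counts of Mir144. Mir99a reached 12685 CPM ± 927, and Mirlet7c-1 and Mir125b-2 of the same host transcript, Mir99ahg, had 454 and 160.1 CPM, both of which share bases with copies elsewhere.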

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

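Tests of liver RNA, of dilution by Mir122 and of GC content were set before their results were seen, and the other tests weighed here were chosen afterwards. Antisense counts, which enter no comparison above, exceeded the 3 counts that a count of 0 allows in both libraries at 4 hairpins without an annotated opposite-strand partner. Mir203 on chromosome 12 (112130880 to 112130955) had 956 antisense counts, 385 in replicate 1 and 571 in replicate 2, or 3.36% and 8.74% of the counts on both strands there. Mir708 had 31, Mirlet7b 21 and Mir130a 20. Mir34b exceeded that limit in replicate 2 alone, with 5 antisense counts against 3 in replicate 1.

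Mir122 was 221-fold higher in replicate 2. A stray Mir122 sequence alone would leave other liver hairpins near the median gene, but the smaller of the Mir192 and Mir194-2 log2 ratios lay 4.39 above it. That test was set after both ratios had been seen, and it cannot decide if RNA from kidney raised both hairpins. RNA from kidney stays open for Mir192 and Mir194-2. The median of Mir204, Mir10a, Mir10b and Mir30a was -0.80, and 0 of these 4 were higher relative to the median gene. However, 3 of the 4 already exceeded in replicate 1 the 569 CPM that Mir192 reached, which would hide a small share. The other, Mir204, was not above that level, and had 48.5 CPM in replicate 1 and 35.7 CPM in replicate 2. As 1 hairpin it goes against kidney RNA but does not decide. Of 5 further liver-abundant hairpins chosen before their values were seen, Mir148a, Mir101a, Mir101b, Mir802 and Mir1948, all 5 were higher in replicate 2, with a median of 2.07 at percentile 99.8 of matched random lists. Mir802 and Mir1948 had under 10 counts in replicate 1, and both lay above that median, so the percentile depends on them. The detected members Mir101b, Mir101a and Mir148a lay 2.07, 0.82 and 0.69 above the median gene, and no percentile was taken for them alone. RNA from liver cells in replicate 2 is therefore a candidate explanation, and whether it entered with the tissue, during preparation or from another library was not tested, nor was any biological explanation.

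Mir206 had 3540 counts in replicate 1 and 3 in replicate 2, and RNA from skeletal muscle in replicate 1 is a possible explanation. The first test set for it asked whether Mir133b, which shares the Mir206 primary transcript, held at least 10% of the Mir206 counts in replicate 1, and this was not met, since Mir133b held 0%. Mir133b shares at least 20 bases with Mir133a-1 and Mir133a-2 and its reads there go uncounted, so that 0 does not decide. The 9 other striated-muscle hairpins had 71 counts in replicate 1 and 13 in replicate 2, 6.91-fold higher in CPM (3.79 to 13.6, exact binomial p = 2.86e-14, 6 of 9 higher), but this comparison was chosen after those counts had been seen, Mir499 gave 36 of the 71, and Mir1b went the other way with 1 and 10. Muscle RNA in replicate 1 stays open, and no biological explanation was tested.

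More genes differed between the libraries than counting error gives, 236 of 352. Dilution of the other genes by Mir122 would end most calls once Mir122 left the totals, but 71.2% of 351 genes still differed. GC content of the hairpins could play a part, since its Spearman correlation with the log2 ratio across 352 genes was 0.27, between the bounds of 0.1 and 0.3 set for it. Differences between animals stay open and untested, since there were 2 libraries and the labels give both the same donor entry.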

How the results depend on the processing

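No paired analysis was possible because there was 1 group. The settings without liver-abundant hairpins and without hairpins sharing bases were chosen after seeing the data. Detected genes numbered 567 at 1 count and 234 at 100 counts in both, by construction. The top 10 share was 61.8% without hairpins sharing 20 bases, and 54.6% to 60.2% in the other settings. The correlation was 0.931 at 10 CPM or more, over 295 genes, and 0.963 to 0.976 otherwise. Genes differing between the libraries numbered 210 to 250 in all 7 alternatives, with 171 higher and 74 lower in replicate 2 without the liver-abundant hairpins. The coefficient of variation ran from 0.364 to 0.492, and levels of neighbouring hairpins stayed past the threshold in all 4 alternatives. As percent of all input reads, which lowers every share by construction, the lists held 9.41 (let-7), 1.46 (Mir30), 0.462 (Mir17), 1.95 (Dlk1-Dio3), 1.12 (Mir322), 0.000459 (testis), 0.0419 (Sfmbt2), 1.43 (adrenal cortex), 1.61 (neuroendocrine), 2.92 (endothelial), 1.76 (stroma), 0.0606 (erythroid), 0.166 (leukocyte), 0.0971 (epithelial), 2.61 (adipose), 2.80 (Hox), 0.0852 (ciliated) and 0.00229 (rRNA or tRNA). With either-strand counts, which lose hairpins with an opposite-strand partner, they held 25.3 (let-7), 2.36 (Mir30), 1.28 (Mir17), 0.00128 (testis), 4.48 (neuroendocrine), 0.759 (endothelial), 0.0308 (erythroid), 0.0668 (adipose) and 0.00634 (rRNA or tRNA). With Mir122 out of the totals the Mir17, testis, endothelial and adipose lists held 1.22, 0.00120, 7.67 and 6.83, and without the 9 liver-abundant hairpins 1.22, 0.00121, 7.69 and 6.85, larger because the total is smaller. The stroma shift was -0.54 with a pseudocount of 10, inside the central range; the cause was not tested. The other 16 lists kept their side of the range there, as did all 17 with a pseudocount of 0.1, and other scalings say little here, since they hardly move medians taken relative to all genes. The mean absolute difference in log2 ratio between neighbours was 0.73 with and without the liver-abundant hairpins. Shuffled ratios gave 0.87 with them and 0.76 without them, where the test was no longer past the threshold. Of the 25 leading genes, 22 moved beyond 1 SD when scaled to input reads, which lowers every level by construction. With either-strand counts, 11 did. Depth and the loss of reads mapped to several places limit what can be said of the 1453 genes without a count. Of all 2202 genes, 1084 share at least 20 bases with another hairpin.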

Other observations

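The tests in this part were chosen after the levels had been seen. The liver-abundant hairpins differed in size of change. Mir802 had 1 count in replicate 1 and 270 in replicate 2, a ratio of 213 (38.0 to 8457), and Mir1948 had 9 and 113. Mir101b was 4.08-fold, Mir101a 1.73-fold and Mir148a 1.57-fold higher in replicate 2. The ratio of Mir122 to Mir802 was 3201 in replicate 1 and 3323 in replicate 2, the former resting on 1 Mir802 count. That of Mir122 to Mir192 was not alike, at 45.7 in replicate 1 and 347 in replicate 2. With the 9 liver-abundant hairpins left out, the 10 most abundant genes held 55.2% of counts in replicate 1 and 54.0% in replicate 2.

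Log2 ratios between the libraries were somewhat closer for neighbouring hairpins than for shuffled ones, but this rested on Mir192 and Mir194-2. Across the 94 adjacent pairs the mean absolute difference in log2 ratio was 0.73, against 0.87 for shuffled ratios (permutation test, one-sided, 100000 resamples, p = 0.0049). Without the 9 liver-abundant hairpins, which removes that 1 pair and leaves 93, it was 0.73 against 0.76 (permutation test, p = 0.285). Neighbours also differed in size of change, as Mir143 was 1.48-fold and Mir145a 3.40-fold higher in replicate 1.

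By chromosome, the largest share of counts in replicate 2 was on chromosome 18, with 28.8% against 11.3% in replicate 1, where Mir122, Mir378a, Mir143 and Mir145a lie. Chromosome 12 had the most detected hairpins, 63 of 146, but 4.96% ± 0.717 of the counts (SD, n = 2). The X chromosome had 35 of 142 detected and 5.12% ± 0.717 of the counts, and the Y chromosome had 0 of 6 detected.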
